A study of Mus musculus with 24 samples.

How the data were processed

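Total RNA of 24 samples was measured on 1-colour (Cy3) Agilent mouse arrays, in 6 groups of 4. The NaHS experiment (16 arrays) held vehicle and NaHS at 6 h and 24 h, and the GYY4137 experiment (8 arrays) held GYY4137 in 21% and 85% O2 at 24 h. Per the file headers, the intensity values are processed signals of Agilent Feature Extraction 10.7.3.1, with the background subtracted and spatial and multiplicative trends removed, small values replaced by a surrogate, and no normalization between arrays. The deposited value table holds log2 values, read here as quantile normalized by the authors within each experiment. Its steps are not stated, and this reading rests on its values. The median is 5.947 on all 16 arrays and 7.074 on all 8, which median centring would also give. Genes called for 24 h against 6 h in vehicle numbered 155 with the deposited table, 156 with quantile normalization and 2 with median centring. The table is blank for 10091 probes of the NaHS experiment and 6013 of the GYY4137 experiment. The flags for background, saturation and uneven spots are those of Feature Extraction, per the file headers.

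The main values were computed from the processed signal of each spot. Of 62976 spots, 59305 were not controls and stood for 55681 probes. Spots marked as uneven or as replicate outliers were left out, 0 spots were saturated, and the spots of 432 probes with more than 1 spot were averaged as log2. From each array its own 75th percentile was subtracted. A probe was kept in an experiment when at least 4 of its arrays lay well above background. Of several probes of a gene, the one with the highest mean stood for the gene, and probes without a gene name were kept on their own. This left 33128 genes or unnamed probes in the NaHS experiment, 21382 of them named, and 34515 in the GYY4137 experiment, 21972 of them named. Of the probes 27428 were named through their accession, 3483 through the symbol, 507 through an older symbol and 5243 by the array design, and 19020 had no gene name. The newer of 2 versions of the design was used, which differ in the gene name of 1151 spots, and its probe coordinates are on mm9. In 85% against 21% O2, 20 of 5623 genes with more than 1 probe had probes called in both directions, and 0 of 5534 had any in the other comparisons.

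Each experiment was fitted on its own with limma 3.58.1 in R 4.3.3, with a mean for each group and moderated t statistics, and Benjamini-Hochberg adjustment at 0.05 over all genes of a comparison. Tables were read with the R package data.table (version 1.17.8). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the annotation and the figures. The comparisons were NaHS against vehicle at 6 h and at 24 h, the difference between these effects, 24 h against 6 h in vehicle and in NaHS, and 85% against 21% O2 with GYY4137. The last comparison holds slide and oxygen level together, and no donor-free arrays stood in that experiment. For a gene above background on no array of 1 group and on some of the other, the fold is given as a bound against the dimmest signal called above background on each array of that group, written as at least. This bound is taken between group means and holds no sampling error, so it is not a confidence limit.

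Gene lists were written before the data were examined, and 30 of 31 were tested with camera, at a preset correlation of 0.01 and again with the correlation estimated from the data. The 31 lists are alveolar type II, alveolar type I, transitional and injured alveolar epithelium, NRF2 antioxidant, H2S production and oxidation, ATF4 integrated stress response, endoplasmic reticulum unfolded protein response, heat shock, HIF target, p53 target, proliferation, NF-kB inflammatory, interferon response, matrix and TGF-beta, cholesterol synthesis, fatty acid and phospholipid synthesis, mitochondrial respiration, DNA repair, metal response, circadian clock and immediate early genes, and markers of macrophages, lymphocytes, neutrophils, fibroblasts, smooth muscle, endothelium, club, ciliated, basal and erythroid cells. Lists under 4 measured genes were not tested, which left out the erythroid list. Genes were also adjusted over each list alone. The lists share genes, and many markers are not unique to 1 cell type.

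The genes to be named were set by a rule written before the data were examined. It takes, per comparison, the 12 largest rises and 12 largest falls among called genes with a usual gene symbol. Where fewer than 6 genes passed it takes the 5 positive and 5 negative differences with the smallest p. It adds up to 4 members of each list by p, the H2S genes Cbs, Cth, Mpst, Sqor and Ethe1, and Sftpc, Sftpb, Abca3 and Ager.

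The slides differed. With group in the fit, limma called 16691 genes between slide 1 and slide 2, 11786 higher and 4905 lower on slide 2, and 64.2% of the variance of the NaHS experiment lay on the first principal component, which parts those slides. Each NaHS experiment group had 2 arrays on each of them, replicates 1 and 3 on slide 1 and 2 and 4 on slide 2. Whether replicate numbers pair the samples was checked from the correlation of deviations from the group means. Arrays with the same number correlated at 0.536 to 0.754 over 24 pairs in the NaHS experiment, where different numbers on the same slide gave 0.42 to 0.702 and arrays on different slides -0.747 to -0.467. In the GYY4137 experiment the same numbers gave 0.183 to 0.257 over 4 pairs and different numbers -0.216 to 0.165 over 12. In the GYY4137 experiment the numbers were therefore taken to pair the samples. There each replicate number also sat in the slide column of the same number, so pairing cannot be told apart from array position. In the NaHS experiment the ranges of same and different numbers on a slide overlapped, so pairing beyond the slide is not shown. The main fits use neither slide nor pairing, so their spread between samples holds these differences. Slide and replicate number enter only as blocks in the alternatives. The pairing comes from the data, since the labels do not say what a number marks.

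The fits were tested on simulated data, with 250 genes changed at each of 4 folds over 5 rounds. For NaHS against vehicle at 6 h, the comparison simulated in the NaHS experiment, 40% of 2-fold changes and 63.2% of 4-fold changes were called, 53.2% and 81.6% with slide as a block. In the GYY4137 experiment, 39.6% and 78.4% were called. All calls had the right direction, and 1.2, 6.4 and 5.4 unchanged genes were called per round.

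The alternatives were a log2 fold change of at least 1, normexp background subtraction with an offset of 50, quantile normalization, median centring, the deposited value table, no filter on dim probes, a probe above background on all 4 arrays of a group, the mean of a gene's probes, every probe on its own, outlier spots kept, limma with trend and robust, array weights, the replicate number as a block, slide as a block, only the groups compared, and each array left out in turn. Fits within each slide and fits of bright genes alone were added after the data were seen.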

Results

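The arrays measured messenger RNA in primary mouse alveolar type II cells, the lung cells that make and recycle surfactant, after culture at an air-liquid interface for 3 days. Cells of the NaHS experiment received the medium vehicle or 100 µM NaHS, a salt that releases hydrogen sulfide (H2S) quickly, for 6 h or 24 h. Cells of the GYY4137 experiment received 100 µM GYY4137, a compound that releases H2S slowly, for 24 h in 21% or 85% O2. No donor-free group stood beside them here. Each of the 6 groups held 4 arrays, 16 in the NaHS experiment and 8 in the GYY4137 experiment. On each array, between 54.8% and 77.5% of the probes lay well above background, with 54.8% to 57.2% on slide 1, 67.7% to 73.9% on slide 2, 71.4% to 77.1% on slide 3 and 69.4% to 77.5% on slide 4. Slides 1 and 2 each carried 2 arrays of every NaHS experiment group, slide 3 carried the 21% O2 group and slide 4 the 85% O2 group. The labels do not say whether replicates were separate cultures or animals, so each p measures the spread between these samples.

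Most alveolar type II genes were measured above background, as were many markers of other lung cells. These counts alone therefore do not show the cell type. Of 25 alveolar type II genes on the array, 22 lay above background on all 16 arrays of the NaHS experiment and 22 on all 8 arrays of the GYY4137 experiment, as did 20 of 21 alveolar type I genes in each. Sftpc, which encodes surfactant protein C, had a mean log2 signal of 3.91 ± 0.85 (SD, n = 4) over the array's 75th percentile in the vehicle group at 6 h and 1.36 ± 1.002 (SD, n = 4) at 24 h. Abca3, the lipid transporter of the surfactant-storing lamellar bodies, stood at 3.15 ± 0.44 and 3.13 ± 0.08 (SD, n = 4) in the same groups. The surfactant protein genes Sftpb and Sftpa1 were dimmer there. Sftpb stood at 0.37 ± 0.61 and -1.505 ± 0.88, and Sftpa1 at -1.83 ± 0.43 and -4.97 ± 0.68 (SD, n = 4). At 24 h Sftpa1 lay above background on 3 of 4 vehicle arrays. Markers of other lung cells were also measured above background on all 16 arrays, with 10 of 11 smooth muscle genes, 15 of 17 fibroblast genes, 6 of 8 basal cell genes, 13 of 18 macrophage genes, 9 of 14 ciliated cell genes, 9 of 15 endothelial genes, 6 of 11 neutrophil genes, 5 of 12 club cell genes, 5 of 14 lymphocyte genes and 1 of 6 erythroid genes. Below, changes are log2 fold changes ± standard error from limma with 4 arrays per group, and list tests are camera tests with a preset correlation unless an estimated correlation is named.

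**Figure D1:**
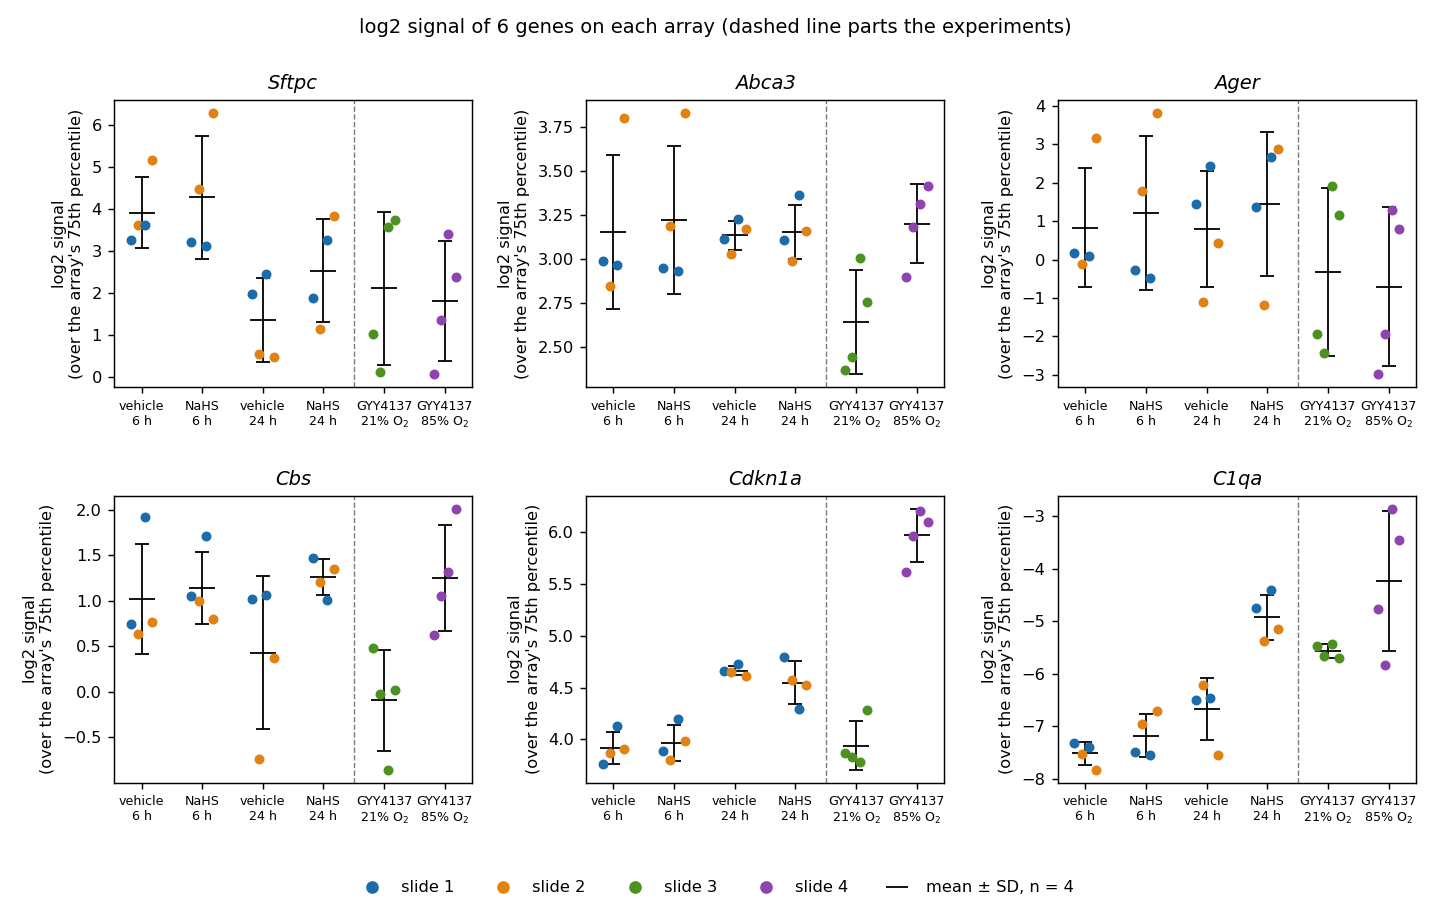
The log2 signal over the array's 75th percentile (vertical axis) of 6 genes on each of the 24 arrays, by group (horizontal axis); points are arrays coloured by slide, bars show the mean and SD of 4 arrays, and the dashed line parts the experiments. Cdkn1a averages 3.94 in 21% O2 and 5.97 in 85% O2, and C1qa lies above background on 4 of 4 arrays with NaHS at 24 h and on 0 of 4 in each other NaHS experiment group.

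The comparison of NaHS with vehicle at 6 h asks what the fast donor does early. The genes that make or oxidise H2S showed no change past the threshold. Cbs and Cth, enzymes that release H2S from sulfur amino acids, differed by 0.12 ± 0.38 and 0.12 ± 0.63. Mpst differed by 0.01 ± 0.13, Sqor, the mitochondrial enzyme that begins H2S oxidation, by -0.05 ± 0.16, and Ethe1 by -0.03 ± 0.14. The 95% interval of the difference ran from -0.70 to 0.95 for Cbs and from -0.41 to 0.30 for Sqor. Among genes of cell identity, Sftpc differed by 0.37 ± 0.78, Sftpb by 0.08 ± 0.55, Abca3 by 0.07 ± 0.22 and the type I cell gene Ager by 0.38 ± 1.18, none past the threshold. limma called 0 of 33128 genes at an adjusted p under 0.05, with 196 at an unadjusted p under 0.05. The named genes with the smallest p, none past the threshold, were Mpp2 (0.44 ± 0.13), Brsk2 (0.95 ± 0.30), Tas2r118 (1.63 ± 0.52), Myoz1 (0.58 ± 0.19) and Wdr25 (0.34 ± 0.12) with positive differences. Those with negative differences were Setmar (-0.25 ± 0.07), Spata48 (-0.52 ± 0.16), Bnipl (above background on 1 of 4 NaHS arrays), Iqgap2 and Prph. Iqgap2 and Prph lay above background on 0 of 4 NaHS arrays, at least 1.18-fold and 1.46-fold lower.

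The 22 genes of cholesterol synthesis had a median of -0.25 at 6 h with 0 of 22 positive, among them Idi1 (-0.43 ± 0.28), Mvk (-0.32 ± 0.20) and Hsd17b7 (-0.32 ± 0.15), none past the threshold. The preset-correlation test of this list gave an adjusted p = 4.43e-09. The call was lost at adjusted p = 0.743 with an estimated correlation. The preset test also called the fibroblast list lower (median -0.24, adjusted p = 0.000143), with Inmt at -0.59 ± 0.24 and Meox2 at -1.36 ± 0.55, neither past the threshold. It called the ciliated list lower (median -0.36, adjusted p = 0.000493), with Tppp3 at -0.47 ± 0.26, and the endothelial list higher (median 0.22, adjusted p = 0.00912). These 3 lists had adjusted p = 0.73 with an estimated correlation. The alveolar type I list (median 0.27) was called higher at adjusted p = 0.0373. The HIF target (-0.06), proliferation (-0.07) and club cell (-0.27) lists were called lower at 0.0171, 0.0171 and 0.0408. These 4 calls were lost at adjusted p = 0.918 with an estimated correlation. In each of these 8 lists, 0 genes passed when adjusted over the list alone. With slide as a block, 0 genes passed (629 at an unadjusted p under 0.05). Within slide 1 and within slide 2, with 2 arrays per group, 0 and 0 passed (1095 and 514). The 95% interval of the difference lay within a 2-fold change either way for 19299 genes, 58.3% of those tested, and for 25186 with slide as a block. NaHS and vehicle arrays also sat in different columns of each slide.

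At 24 h, the comparison of NaHS with vehicle asks for the later response. C1qa, a complement gene of macrophages, was among the genes with the smallest p but did not pass (adjusted p = 0.9998). It lay above background on 4 of 4 NaHS arrays and 0 of 4 vehicle arrays, at least 1.71-fold higher. Its log2 difference was -0.03 when the background was subtracted by normexp. Cbs differed by 0.83 ± 0.38, with a 95% interval from 0.0035 to 1.66, but did not pass (adjusted p = 0.9998). Cth differed by -0.03 ± 0.63, Mpst by -0.13 ± 0.13, Sqor by 0.26 ± 0.16 and Ethe1 by -0.06 ± 0.14. The surfactant genes Sftpc (1.17 ± 0.78), Sftpb (0.91 ± 0.55), Sftpa1 (0.96 ± 0.51) and Abca3 (0.02 ± 0.22), the NRF2 target Nqo1 (0.61 ± 0.34) and the type I gene Ager (0.64 ± 1.18) did not pass either. limma called 0 of 33128 genes, with 734 at an unadjusted p under 0.05. Besides C1qa, the smallest p belonged to Kit (1.22 ± 0.25), Nefm (at least 1.83-fold higher), Arl14 (at least 3.69-fold higher), Olfr187 (0.78 ± 0.21), Tchh (-0.71 ± 0.14), Apol7a (-0.54 ± 0.15), Neu3 (-0.51 ± 0.15), Drd4 (-0.94 ± 0.28) and Olfr616 (at least 1.16-fold lower), none past the threshold. With normexp the differences of Kit (-0.033), Nefm (-0.060) and Olfr187 (-0.0099) also turned negative. The C1qa probe lies on chromosome 4 from 136452409 to 136452468 (mm9).

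Among the lists at 24 h, 26 of 27 proliferation genes had positive differences (median 0.23; Bub1 0.34 ± 0.15 and Mcm5 0.35 ± 0.17, neither past the threshold), with an adjusted p = 2.35e-08, lost at adjusted p = 0.716 with an estimated correlation. The p53 target list was called lower (median -0.13, 2 of 25 positive, adjusted p = 9.58e-06; Eda2r -0.49 ± 0.18, not past the threshold), lost at adjusted p = 0.082 with an estimated correlation. The alveolar type II list was called higher (median 0.49, 20 of 24 positive, adjusted p = 0.000609), as were DNA repair (median 0.12, 0.00564) and immediate early genes (median 0.15, 0.0478). Each call was lost at adjusted p = 0.716 with an estimated correlation. The interferon (median -0.21, adjusted p = 0.000631; Isg15 -0.60 ± 0.22, not past the threshold), matrix (-0.09, 0.00564) and smooth muscle lists (-0.25, 0.00777) were called lower. Each was lost at adjusted p = 0.716 with an estimated correlation. Cholesterol synthesis was called lower too (-0.16, adjusted p = 0.00262), lost at adjusted p = 0.763 with an estimated correlation. Adjusted over the list alone, 1 macrophage gene, C1qa, passed, while the macrophage list had a median of -0.25 and was not called. With slide as a block 0 genes passed (2896 at an unadjusted p under 0.05, smallest adjusted p 0.307), and within slides 1 and 2 0 and 0 passed (1351 and 3374). The 95% interval lay within a 2-fold change either way for 18415 genes (55.6%), or 23782 with slide as a block.

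Whether the NaHS effect differed between the times was tested directly, as the effect at 24 h minus that at 6 h. Among the named genes with the smallest p were Cenpm (0.51 ± 0.13), a centromere protein gene, Itga2b (0.97 ± 0.26), P4ha3 (0.55 ± 0.15), Tchh (-0.65 ± 0.19), Mpp2 (-0.61 ± 0.19), Apol7a (-0.70 ± 0.21), Tenm3 (-0.58 ± 0.18) and Drd4 (-1.21 ± 0.39), none past the threshold (each adjusted p = 0.99998). Iqgap2, above background on 0 of 4 arrays in NaHS at 6 h and in vehicle at 24 h, and Bnipl, on 0 of 4 in vehicle at 24 h, also had small p but are given no size. limma called 0 genes, with 356 (1.07%) at an unadjusted p under 0.05, and 0 with slide as a block (1557). The proliferation list differed by a median of 0.30 between the times (adjusted p = 2.96e-10), lost at adjusted p = 0.81 with an estimated correlation, and the p53 list by -0.12 (adjusted p = 0.000146), lost at adjusted p = 0.178 with an estimated correlation. In both lists 0 genes passed, also when adjusted over the list alone.

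The vehicle groups give the change with time in culture without a donor. From 6 h to 24 h, 5 of 25 p53 target genes rose and 5 of 27 proliferation genes fell. Cdkn1a, the cell cycle inhibitor p21, rose by 0.75 ± 0.12 (adjusted p = 0.024), Eda2r by 1.10 ± 0.18 (0.0256), Zmat3 by 0.57 ± 0.10 (0.0298) and Ccng1 by 0.52 ± 0.11 (0.0473). Mcm5, part of the replication helicase, fell by 0.88 ± 0.17 (0.0374), Birc5 by 0.81 ± 0.16 (0.0449), Kif20a by 0.72 ± 0.14 (0.038) and Cdca3 by 0.86 ± 0.17 (0.0468). Among the genes with the largest falls were Sftpa1, surfactant protein A, at -3.14 ± 0.51 (0.024), the secretoglobin Scgb3a1 at -3.72 ± 0.68 (0.0333), the mucosal peptide gene Tff1 at -3.07 ± 0.50 (0.0233) and lactoferrin, Ltf, at -2.05 ± 0.37 (0.0318). The basement membrane collagen genes Col4a1 and Col4a2 rose, by 0.97 ± 0.15 (adjusted p = 0.0216) and 0.85 ± 0.14 (0.0265). limma called 201 genes, 128 higher and 73 lower, of which 32 and 18 changed at least 2-fold. Further genes that rose were Cd53 (2.34 ± 0.31), Gabrb1 (2.22 ± 0.33), the cell cycle inhibitor gene Cdkn2a (1.94 ± 0.37), Ctla2a (1.73 ± 0.28), Ctla2b (1.58 ± 0.27), Dmpk (1.51 ± 0.29), Drd4 (1.40 ± 0.28), Serpina5 (1.36 ± 0.28), Efhd1 (1.29 ± 0.27), Notch3 (1.24 ± 0.16), Nacad (1.23 ± 0.22) and Dysf (1.21 ± 0.25). Further genes that fell were Anxa10 (-2.79 ± 0.57), Zfp474 (at least 3.07-fold lower), Krtap1-5 (-2.24 ± 0.43), the matrix protease gene Mmp3 (-2.22 ± 0.42), Cilp (-1.94 ± 0.27), Tmprss13 (-1.60 ± 0.29), Ccno (-1.39 ± 0.24) and Depdc1b (-1.12 ± 0.18). The probes lie on chromosome 17 from 29237377 to 29237436 for Cdkn1a and on chromosome 14 from 41947507 to 41947566 for Sftpa1 (mm9). The probe named Tff1 is placed on chromosome 5 from 143285582 to 143285641, and its name was not checked against that position.

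By list, 5 of 25 p53 target genes rose with time and 0 fell, 10 and 0 when adjusted over the list alone, and the list was called at adjusted p = 1.5e-14 and at adjusted p = 0.0017 with an estimated correlation. Of 27 proliferation genes 5 fell and 0 rose, 23 and 0 when adjusted over the list alone (adjusted p = 6.7e-26), lost at adjusted p = 0.18 with an estimated correlation. In the ATF4 stress list 27 of 28 genes had positive differences (median 0.54, adjusted p = 3.69e-12). Of these 0 passed over all genes and 9 when adjusted over the list alone, among them Pck2 (0.86 ± 0.20, adjusted p = 0.0689), Sesn2 (0.46 ± 0.11, 0.0862) and Vldlr (0.88 ± 0.24, 0.119). The call was lost at adjusted p = 0.329 with an estimated correlation. The DNA repair list was lower (median -0.23, adjusted p = 4.02e-06; 0 genes passed and 5 when adjusted over the list alone), lost at adjusted p = 0.329 with an estimated correlation. The alveolar type II list was called lower (median -0.14, adjusted p = 0.0223), lost at adjusted p = 0.652 with an estimated correlation. In it 1 of 24 genes fell and 4 when adjusted over the list alone. Replicate 4 of vehicle at 6 h stood apart in the mean of this list, at 1.33 against 0.23 to 0.40 on the other 3 arrays. Sftpb (-1.88 ± 0.55, adjusted p = 0.149), Sftpc (-2.55 ± 0.78, 0.176), Cxcl15 (at least 1.77-fold lower, 0.167), Abca3 (-0.02 ± 0.22) and Ager (-0.03 ± 1.18) did not pass. The interferon (median 0.32, adjusted p = 0.00118), matrix (0.16, 0.000507) and HIF target lists (0.13, 0.00456) were called higher, with 2 (Isg15 1.10 ± 0.22 and Ifi44 0.92 ± 0.17), 2 and 0 genes past the threshold. The calls were lost at adjusted p = 0.469, 0.507 and 0.507 with an estimated correlation. Adjusted over the list alone, 3 interferon, 3 matrix and 3 HIF target genes were higher and 1 interferon gene was lower. Transitional epithelium (-0.14, adjusted p = 0.0213) and immediate early genes (-0.18, 0.012) were called lower with 0 genes past the threshold, lost at adjusted p = 0.543 and 0.442 with an estimated correlation.

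The preset test called lists of other cell types too. The club cell list (median -1.36, adjusted p = 3.34e-05) and the ciliated list (-0.63, 9.52e-06) were called lower, and the smooth muscle list (0.76, 4.87e-09) and the macrophage list (0.84, 0.000455) higher. They were lost at adjusted p = 0.25, 0.324, 0.18 and 0.469 with an estimated correlation. Adjusted over the list alone, 4 club and 3 ciliated genes were lower, 5 smooth muscle genes were higher and 0 macrophage genes passed. Of these, Scgb3a1 and Notch3 passed, and the fibroblast gene Thy1 rose (1.16 ± 0.24, adjusted p = 0.0486), while Bpifa1 (-3.92 ± 0.89, 0.0654) and Scgb1a1 (-2.88 ± 0.77, 0.111) did not. With slide as a block 711 genes passed, all 201 among them. Within slides 1 and 2, with 2 arrays per group, 0 and 1 passed (4348 and 3158 at an unadjusted p under 0.05). The count was 0 when only these groups were fitted, 2 with median centring and between 6 and 308 without 1 array. All 6 h arrays sat in row 1 of the slides and all 24 h arrays in row 2.

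The NaHS groups give the change with time in the presence of the donor. C1qa rose, above background on 4 of 4 arrays at 24 h and 0 of 4 at 6 h and at least 1.62-fold higher (adjusted p = 0.0312). So did Loxl3, a lysyl oxidase gene (1.23 ± 0.15, 0.0312), the transcription factor gene Foxc2 (1.0003 ± 0.14, 0.0412), the DNA repair gene Mgmt (0.76 ± 0.10, 0.0312), Cpq (0.74 ± 0.09, 0.0312) and Ano10 (0.58 ± 0.09, 0.0416). C1qa lay above background on no other array of the experiment, so it passed the filter on dim probes through NaHS at 24 h alone. The histone gene H3c1 fell by 0.82 ± 0.12 (adjusted p = 0.0416) and Rtn4rl1 fell by 0.79 ± 0.11 (0.0416). limma called 9 genes, 7 higher and 2 lower, and the difference from the vehicle groups is the direct test above, which called 0. Cdkn1a (0.59 ± 0.12, adjusted p = 0.149), Sftpa1 (-2.36 ± 0.51, 0.173), Sftpb (-1.05 ± 0.55, 0.767), Sftpc (-1.74 ± 0.78, 0.661), Abca3 (-0.07 ± 0.22) and Ager (0.23 ± 1.18) did not pass. The p53 target list was called higher (median 0.21, adjusted p = 7.66e-08, and adjusted p = 0.0279 with an estimated correlation), with 0 genes past the threshold and 3 when adjusted over the list alone. The ATF4 (median 0.51, adjusted p = 1.61e-14), HIF (0.21, 0.000117), smooth muscle (0.68, 2.99e-06) and macrophage lists (0.62, 0.00342) were called higher. These calls were lost at adjusted p = 0.426, 0.463, 0.413 and 0.713 with an estimated correlation. The proliferation (-0.33, adjusted p = 1.12e-12), DNA repair (-0.14, 0.0128) and club lists (-0.69, 0.00241) were called lower. Their calls were lost at adjusted p = 0.426, 0.713 and 0.426 with an estimated correlation. Adjusted over the list alone, 1 macrophage gene and 1 smooth muscle gene passed, and 0 genes in those of the other 5 lists. With slide as a block 33 genes passed, all 9 among them. There were 0 within slide 1 and 0 within slide 2, 0 when only these groups were fitted, and at most 3 without 1 array.

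The last comparison asks how high oxygen changes cells that are given the slow donor. In 85% O2 the cells had far lower expression of cell division genes than in 21% O2. The histone gene H1f5 fell by 3.78 ± 0.27 (adjusted p = 0.00144), the proliferation marker Mki67 by 2.88 ± 0.29 (0.00192), the mitotic kinase gene Plk1 by 2.86 ± 0.27 (0.00149) and the mitotic motor gene Kif11 by 2.83 ± 0.26 (0.00147). Most genes of the antioxidant and p53 target lists rose. Nqo1, a quinone reductase, rose by 3.42 ± 0.24 (0.00144), Gsta3, a glutathione transferase, by 2.95 ± 0.59 (0.0165), Cdkn1a by 2.03 ± 0.17 (0.00144) and Mdm2, the ubiquitin ligase that limits p53, by 1.81 ± 0.15 (0.00144). limma called 5453 of 34515 genes, 3536 higher and 1917 lower, of which 1463 and 751 changed at least 2-fold. With quantile normalization the split was 2716 higher and 2569 lower, and with median centring 2416 higher and 2465 lower. With normexp background it was 3307 higher and 2661 lower, so the surplus of higher genes was smaller or absent under these settings. Other genes with the largest falls were H2bc18 (-3.40 ± 0.48), Ska1 (-3.08 ± 0.32), Aspm (-3.02 ± 0.22), Ndc80 (-2.95 ± 0.23), Sgo2a (-2.84 ± 0.29), Knl1 (-2.83 ± 0.33) and Fbxo5 (-2.83 ± 0.26), most of them parts of the kinetochore or spindle, and Tnfsf4 (at least 2.81-fold lower). Other genes with the largest rises were Prl2c5 (3.095 ± 0.33), the cornified envelope genes Lce1g (2.98 ± 0.40) and Lce1i (2.91 ± 0.46), Svop (2.87 ± 0.24) and Zfp750 (2.76 ± 0.42). The dim genes H2-M9, Slc2a9, Sprr2g, Vmn2r78 and Krt33a lay above background on 4 of 4 arrays in 85% O2 and 0 of 4 in 21% O2, at least 7.82-fold, 3.13-fold, 6.5-fold, 5.96-fold and 3.6-fold higher. They passed the filter on dim probes through 85% O2 alone, and Tnfsf4 through 21% O2 alone. The probes lie on chromosome 8 from 109912440 to 109912499 for Nqo1, chromosome 7 from 142881591 to 142881650 for Mki67 and chromosome 13 from 21871923 to 21871982 for H1f5 (mm9).

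**Figure D2:**
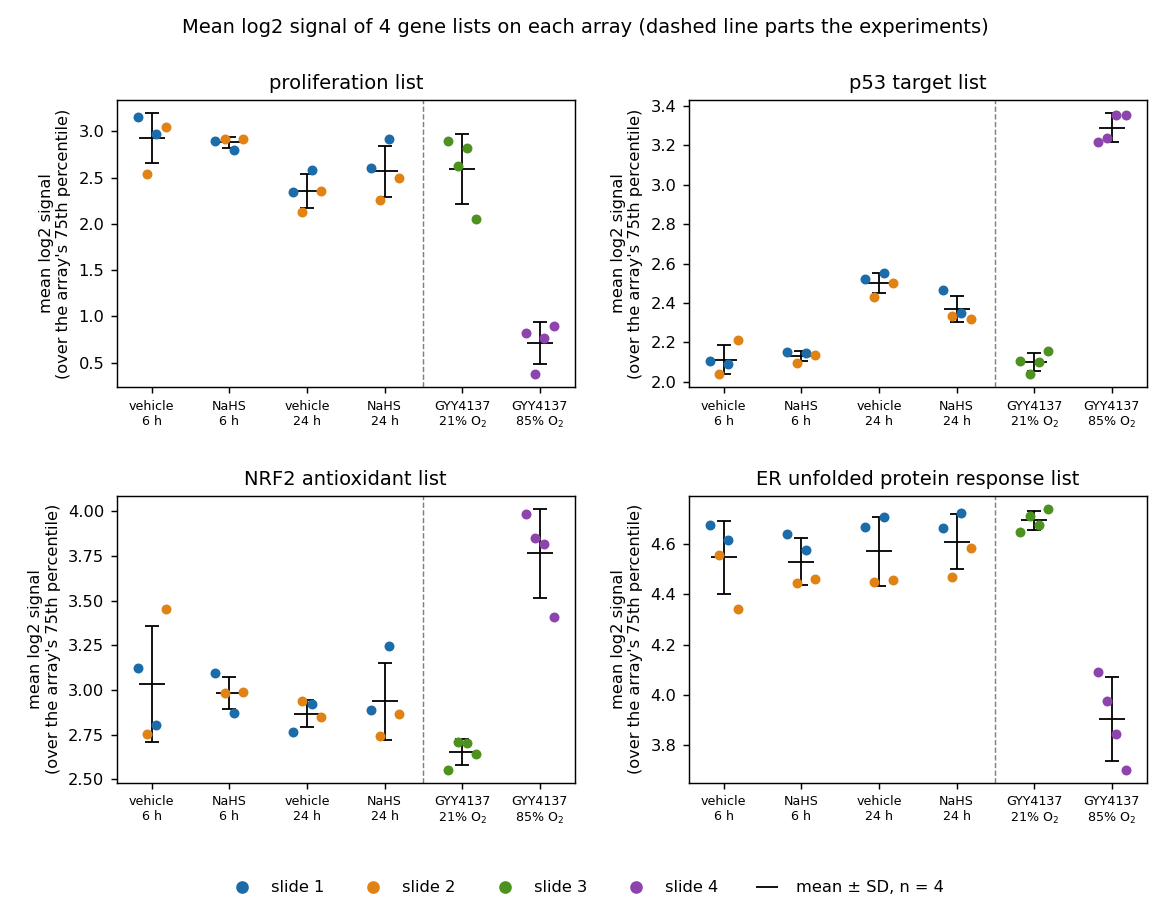
The mean log2 signal over the array's 75th percentile (vertical axis) of 4 gene lists on each of the 24 arrays, by group (horizontal axis); points are arrays coloured by slide, bars show the mean and SD of 4 arrays, and the dashed line parts the experiments. For the p53 target list the 85% O2 arrays lie between 3.22 and 3.36 and the 21% O2 arrays between 2.04 and 2.15.

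By list, 26 of 27 proliferation genes fell and 0 rose, also 26 and 0 when adjusted over the list alone, among them Ccna2 (-2.81 ± 0.25), Cdk1 (-2.37 ± 0.21) and Ccnb2 (-2.28 ± 0.21). The list had a median of -2.02 and an adjusted p = 6.1e-26, lost at adjusted p = 0.235 with an estimated correlation. Of 25 p53 target genes 21 rose and 0 fell, 23 and 0 when adjusted over the list alone, among them Dcxr (1.98 ± 0.12) and Zmat3 (1.16 ± 0.10). The list had a median of 1.16 and was called at adjusted p = 1.34e-14 and at adjusted p = 0.013 with an estimated correlation. Of 25 NRF2 antioxidant genes 18 rose and 0 fell, 19 and 0 when adjusted over the list alone, among them Osgin1 (1.54 ± 0.15), the glutathione synthesis gene Gclc (1.41 ± 0.11) and Pgd of the pentose phosphate pathway (1.28 ± 0.14). The list had a median of 1.04 and an adjusted p = 2.21e-10, lost at adjusted p = 0.216 with an estimated correlation. In the unfolded protein response of the endoplasmic reticulum 13 of 18 genes fell and 0 rose, 18 and 0 when adjusted over the list alone, among them Creld2 (-1.33 ± 0.12), Dnajc3 (-1.26 ± 0.17), Sdf2l1 (-1.24 ± 0.15) and Manf (-1.04 ± 0.11). The median was -0.75 and the adjusted p = 6.08e-13, lost at adjusted p = 0.216 with an estimated correlation. Of 26 DNA repair genes 15 fell and 0 rose, 17 and 1 when adjusted over the list alone, among them Exo1 (-2.41 ± 0.27), Rad51ap1 (-2.10 ± 0.29), Fancd2 (-1.45 ± 0.20) and Pold1 (-1.27 ± 0.18). The list had an adjusted p = 6.46e-10, lost at adjusted p = 0.216 with an estimated correlation.

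Of 22 cholesterol synthesis genes 11 fell and 0 rose, 15 and 0 when adjusted over the list alone, among them Idi1 (-1.30 ± 0.22), Stard4 (-1.30 ± 0.20), Tmem97 (-0.93 ± 0.18) and Sqle (-0.88 ± 0.14). The adjusted p = 1.36e-08 was lost at adjusted p = 0.47 with an estimated correlation. The probe named Tmem97 is placed on chromosome 16 from 22231660 to 22231719 (mm9), and its name was not checked against that position. Of 21 fatty acid and phospholipid synthesis genes 3 fell, 4 when adjusted over the list alone. They were Elovl6 (-1.38 ± 0.33), Srebf1 (-0.55 ± 0.15) and Fads1 (-0.54 ± 0.13), the last pair at adjusted p = 0.0808 and 0.0585 with the replicate block. The list's adjusted p = 0.000574 was lost at adjusted p = 0.254 with an estimated correlation. The HIF target list was called lower (median -0.29, adjusted p = 0.0235) although its 1 gene past the threshold rose and 0 passed when adjusted over the list alone. It was lost at adjusted p = 0.913 with an estimated correlation. Among H2S genes, Cbs rose by 1.34 ± 0.35 (adjusted p = 0.0375, 0.0626 with the replicate block and 0.0523 with median centring). Cth (-0.94 ± 0.62), Mpst (-0.33 ± 0.22), Sqor (0.43 ± 0.14, adjusted p = 0.0634) and Ethe1 (0.24 ± 0.12) did not pass. In that list 2 of 14 genes rose, also 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.862).

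In the alveolar type II list 0 genes rose and 1 of 23, Lamp3 of the lamellar body membrane, fell (-1.04 ± 0.14, adjusted p = 0.00431), also 1 when adjusted over the list alone; its median was 0.21, its mean -0.00022, and its test pointed lower (adjusted p = 0.674). Sftpc (-0.31 ± 0.98), Sftpb (-0.70 ± 0.47), Abca3 (0.56 ± 0.18, adjusted p = 0.0703, 0.0435 with the replicate block) and Ager (-0.38 ± 1.28) did not pass, and the 95% interval for Sftpc ran from -2.56 to 1.94. In the alveolar type I list 0 of 21 genes passed (adjusted p = 0.674). In the transitional epithelium list 3 of 20 genes rose, Cldn4 (1.57 ± 0.39), Fosl1 (1.08 ± 0.18) and Ereg (1.0002 ± 0.23), also 3 when adjusted over the list alone (list adjusted p = 0.862). Clock genes that rose were Nr1d1 (2.23 ± 0.27), Per3 (1.26 ± 0.15), Dbp (1.14 ± 0.22) and Tef (0.83 ± 0.13), 4 of 19 with 1 lower, also 4 and 1 when adjusted over the list alone (list adjusted p = 0.0899). The interferon genes Rsad2 (1.84 ± 0.47), Mx2 (1.40 ± 0.35), Ifit1 (1.14 ± 0.29) and Irf9 (0.45 ± 0.11) rose, 4 of 25 and 5 when adjusted over the list alone, but their adjusted p lay between 0.0512 and 0.0664 with the replicate block (list adjusted p = 0.349). The iron genes Slc40a1 (1.23 ± 0.24) and Tfrc (1.16 ± 0.30, adjusted p = 0.0712 with the replicate block) rose in the metal list (2 of 8, list adjusted p = 0.904). Csf3 (2.30 ± 0.54) rose in the inflammatory list (1 of 21, 0 when adjusted over the list alone, list adjusted p = 0.834). The ATF4 (median -0.25, adjusted p = 0.0504), heat shock (-0.16, 0.0719), matrix (-0.03, 0.226), immediate early (0.05, 0.862) and mitochondrial respiration lists (0.04, 0.904) were not called, with 1, 3, 1, 2 and 1 genes past the threshold. The tests of the last pair pointed lower while their medians were above 0.

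Markers of other cell types differed between the oxygen levels as follows. The fibroblast list was called lower (median -0.40, adjusted p = 0.0194), lost at adjusted p = 0.724 with an estimated correlation. In it 1 of 16 genes, Thy1, was lower (-1.05 ± 0.16), also 1 when adjusted over the list alone. Not called were the smooth muscle (median -0.28, adjusted p = 0.103; Notch3 1.36 ± 0.24 higher and Des -1.29 ± 0.25 lower), endothelial (0.47, 0.798; Tek 1.17 ± 0.28 higher) and lymphocyte lists (0.28, 0.657; Cd8a 0.68 ± 0.12 higher). Not called either were the macrophage (0.46, adjusted p = 0.674; 0 of 18), neutrophil (0.44, 0.834; 0 of 9), club (0.21, 0.756; 0 of 9), basal (0.24, 0.862; 0 of 7, mean -0.16) and ciliated lists (0.02, 0.886; 3 higher, with Foxj1 at 1.46 ± 0.34, and 1 lower, Mlf1 at -1.11 ± 0.19). The erythroid list, with 3 genes measured, had 0 past the threshold and 1 when adjusted over the list alone. With the replicate block 5279 genes passed, 4198 of them among the 5453. The count was 2557 and 3345 without the 21% O2 replicates 2 and 3, and 3496, 2064 and 2474 without the 85% O2 replicates 1, 3 and 4. Slide and oxygen level cannot be told apart, since each slide held 1 oxygen level.

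**Figure D3:**
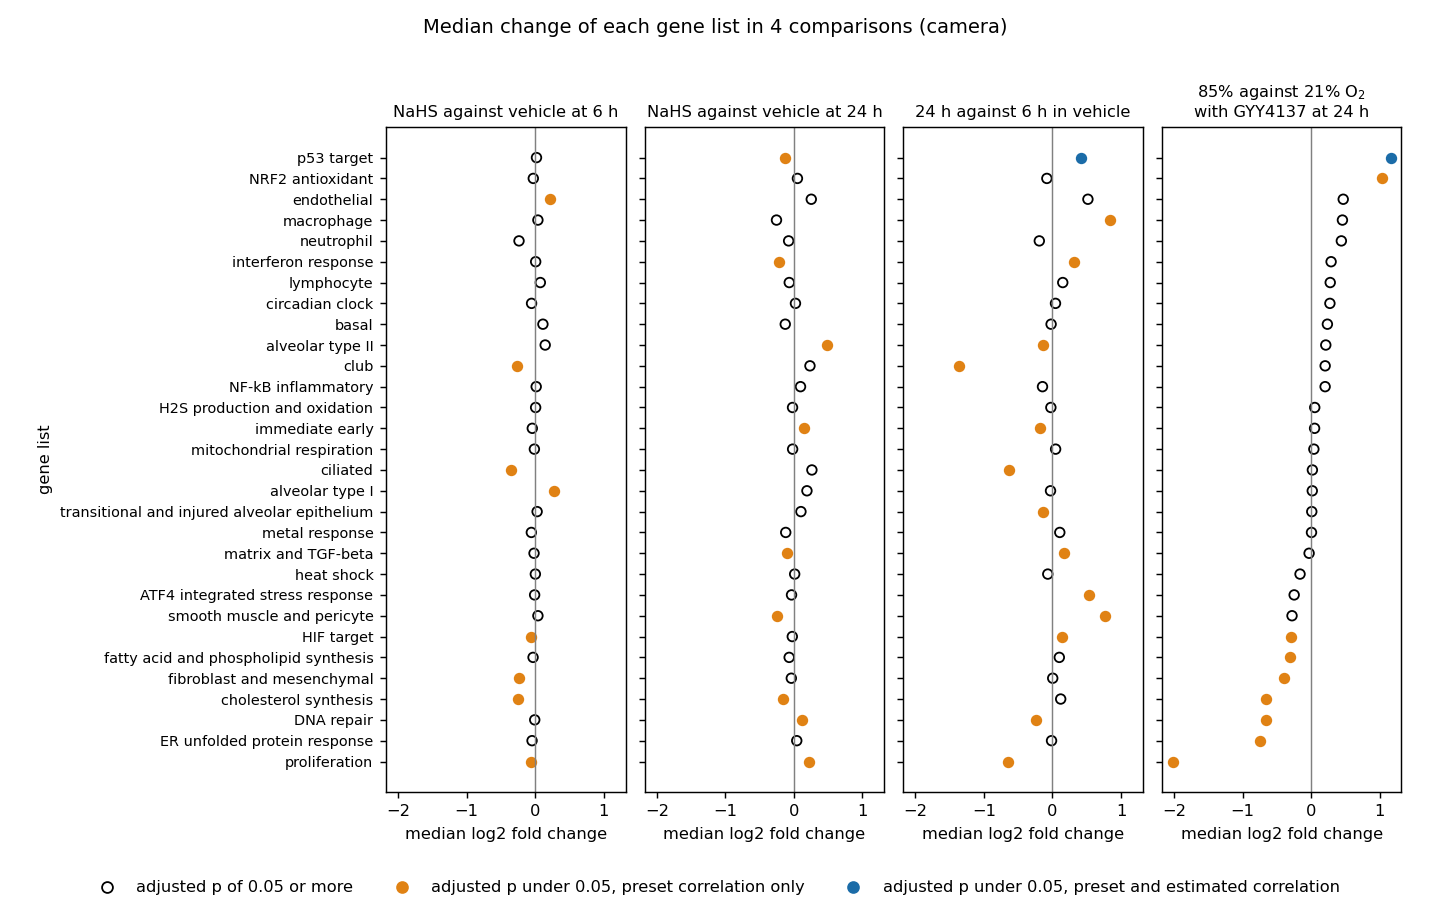
The median log2 fold change (horizontal axis) of each of the 30 gene lists tested (vertical axis) in 4 comparisons; orange points passed an adjusted p of 0.05 in camera with the preset correlation alone, blue points with the preset and the estimated correlation, and open points in neither. The p53 target list is blue in vehicle over time and in 85% against 21% O2, at medians of 0.41 and 1.16, and 0 lists are blue in the NaHS comparisons.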

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

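The tests on another cell type and on dilution of type II cells, on any other difference between the slides and on whether the slides hide NaHS changes were chosen after the result was seen.

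In 85% against 21% O2, proliferation genes fell (list median -2.02) and p53 (1.16) and NRF2 target genes (1.04) rose. A difference of the kind seen between the slides of the NaHS experiment is too small, since the largest of the 3 lists' slide differences was 0.105 of its oxygen change (-0.21 for proliferation, -0.07 for p53 and -0.06 for NRF2). The scaling does not account for it either, as the lists kept at least 0.969 of their medians, taken relative to all genes, under quantile normalization. Dilution of type II cells by another cell type, as the cause of the whole fall, would take the type II list down with it. That list's median was 0.215 ± 0.13, which argues against such dilution as far as the list marks type II cells. Here ± is a standard error of the median over the list's genes, taken as independent, and not over arrays. Many markers are not unique to 1 cell type. Single members were imprecise, as the 95% interval for Sftpc ran from -2.56 to 1.94. Medians of other markers ran from -0.397 ± 0.16 for fibroblasts to 0.47 ± 0.21 for endothelium, with ± again over the genes of a list. That spread fell short of the bound set for it, so it cannot tell whether another cell type made up more of the 85% O2 arrays. A change in the make-up of the cells that leaves the type II list in place stays open. Any other difference between the slides cannot be told apart from oxygen, because 0 slides held both levels, and an effect of oxygen itself stays open beside it.

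No gene passed between NaHS and vehicle at either time. Taking out the slide difference did not bring a gene past the threshold, since limma called 0 genes with slide as a block. With slide as a block the count at an unadjusted p under 0.05 was 629 at 6 h and 2896 at 24 h, against 196 and 734 without it, and this count also rose in other splits that keep the slides balanced. Too little precision to call a 2-fold change stays open, as 53.2% of 2-fold changes simulated for the 6 h comparison were called with slide as a block, with an interval from 46.8% to 59.5%, and none were simulated for 24 h. An absent or small effect of NaHS on these cells stays open as well.

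At 24 h with slide as a block, 2896 genes had an unadjusted p under 0.05 between NaHS and vehicle, more than 5% of those tested. Of the 18 splits that keep the slides balanced, 1, the real one, gave as many, and the highest other gave 2780. With 18 splits the smallest share is 5.56%, too few for a share under 5%. Array-to-array differences shared by many genes therefore cannot be told apart from an effect of NaHS.

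Other splits of the arrays were run for each comparison. For 85% against 21% O2, 1 of 35 splits, the real one with 5453 genes, gave as many and the highest other gave 33. That share is under 5%, but the 35 splits ignore the pairing of replicates taken from these data. Of the 8 splits that part all replicate pairs, the highest other gave 0. As 8 are too few for a share under 5%, chance is not excluded by this count. For 24 h against 6 h in vehicle, 2 of 35 splits gave as many as the real 201, so chance is not excluded by this count. The other was the split that follows the slides, with 7156 genes. With slide as a block the real split gave 711 and the highest other of 18 gave 1, too few splits for a share under 5%. For 24 h against 6 h in NaHS, 2 of 35 splits gave as many as the real 9, the other being the slide split with 4495, so chance is not excluded, and with slide as a block the values were 33 and 0. For NaHS against vehicle, the real split gave 0 at both times, so 35 of 35 splits gave as many at 6 h (highest other 8849) and 35 of 35 at 24 h (highest other 7535), again in the split by slide. For the difference between the NaHS effects, 100 of 100 drawn splits gave as many as the real 0, and the highest other gave 10633. The splits by slide call many times the real counts and point to the slide structure of the arrays. The drawn split with 10633 parts the arrays by slide at 6 h but not at 24 h.

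Of 108 groups of 4 arrays tested, 4 held 1 array far from the other 3, where chance gives about 1 in 20. Cbs was 1.921 on the vehicle 6 h replicate 3 and 0.634 to 0.766 on the other 3. Replicate 4 of the same group stood apart in Abca3 (3.8, others 2.85 to 2.99), in Ager (3.156, others -0.108 to 0.176) and in the mean of the alveolar type II list (1.327, others 0.234 to 0.405).

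The NaHS effect at 24 h differed from that at 6 h in 9 lists by the preset camera test. The medians of the difference were 0.2393 for alveolar type II (adjusted p = 0.0375), -0.1218 for p53 target (0.000146), 0.2972 for proliferation (2.96e-10), -0.1759 for interferon (0.0427), -0.1374 for matrix (0.0375), 0.1119 for DNA repair (0.00831), 0.14 for immediate early (0.0168), -0.1557 for smooth muscle (0.0241) and 0.6754 for ciliated genes (0.000256). With an estimated correlation 0 of the 9 passed, with adjusted p = 0.178 for the p53 list and 0.81 or 0.926 for the others.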

How the results depend on the processing

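The fits within a slide, and those of bright genes alone, were chosen after the data were seen. Where a value moved, the cause was not tested, except that a limit on the fold change can only lower a count.

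For 24 h against 6 h in vehicle (201 genes), the count was 50 with a log2 fold change of at least 1, 505 with normexp background, 2 with median centring, 50 with no filter on dim probes, 527 with probes well above background on all arrays of a group, 120 with the mean of all probes of a gene, 369 with every probe on its own, 451 with eBayes trend and robust, 785 with array weights, 0 with only the groups compared (limma, as throughout), 1367 with slide as a block and only bright genes, 0 within slide 1 and 1 within slide 2. For 24 h against 6 h in NaHS (9 genes), the counts were 3 with a log2 fold change of at least 1, 34 with normexp background, 2 with quantile normalization, 0 with median centring, 2 with series matrix values, 0 with no filter on dim probes, 21 with all arrays of a group, 1152 with array weights, 0 with only the groups compared, 420 with slide as a block and only bright genes, and 0 within slide 1 and 0 within slide 2. For NaHS against vehicle at 24 h (0 genes), array weights gave 1, C1qa at adjusted p = 0.0393, and it passed in no other setting. For 85% against 21% O2 (5453 genes), the count was 2214 with a log2 fold change of at least 1, 8219 with array weights and 2858 with only bright genes.

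With the replicate block, which fits the arrays as paired by their number, 885 genes passed with time in vehicle and 35 with time in NaHS, and with slide as a block 711 and 33. In 85% against 21% O2 the replicate block ended the calls of Cbs, Tfrc, Mx2, Irf9, Rsad2, Ifit1, Fads1 and Srebf1, and 0 genes passed in the NaHS comparisons. Median centring also ended the calls of Cbs and Irf9, quantile normalization those of Ifit1 and Tek, and normexp those of Tnfsf4, Mx2, Ifit1 and Cd8a. No filter ended those of Tnfsf4, Cbs, Tfrc, Irf9, Rsad2, Ifit1, Fads1 and Srebf1, and the mean of probes those of Tfrc and Cd8a.

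Of the list tests, with an estimated correlation 0 of 8 lists remained called for NaHS at 6 h, 0 of 9 at 24 h, 0 of 9 for the difference between these effects, 1 of 14 for time in vehicle, 1 of 8 for time in NaHS and 1 of 9 for O2. Quantile normalization gave 5 lists for the difference between the NaHS effects. For NaHS at 6 h no filter gave 5 lists and the replicate block 3.

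Some genes not past the threshold changed sign. With normexp background these were Ethe1 (0.0054) at 6 h, C1qa (-0.028), Kit (-0.033), Nefm (-0.060), Olfr187 (-0.0099) and Cxcl15 (-0.089) for NaHS at 24 h, and Abca3 (0.026) and Ager (0.00045) with time in vehicle. Median centring gave -0.0014 for Mpst at 6 h. Array weights gave Cbs -0.11, Cth -0.66, Mpst -0.16 and Sqor 0.040 at 6 h, Cth 0.095 at 24 h, Abca3 0.12 and Ager 1.20 with time in vehicle, Ager -0.35 with time in NaHS, and Sftpc 0.41 and Ager 0.50 in O2. Within slide 1, values were Mpst -0.079, Ethe1 0.053, Sftpc -0.26, Sftpb -0.25, Abca3 -0.038 and Ager -0.51 at 6 h, Cth 0.039 and Ethe1 0.00082 at 24 h, Abca3 0.19 and Ager 1.81 with time in vehicle and Abca3 0.29 with time in NaHS. Within slide 2 they were Cth -0.13 at 6 h, Abca3 -0.024 at 24 h and Ager -1.94 with time in NaHS.

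Without 1 array at a time, the count ran from 6 to 308 with time in vehicle, 0 to 3 with time in NaHS, 2064 to 6764 in O2, and stayed at 0 for the NaHS effects. With time in vehicle it was 9, 308, 53 and 62 without replicates 1 to 4 of vehicle 6 h, and 6, 17, 68 and 31 without those of vehicle 24 h. With time in NaHS it was 3 without NaHS 6 h replicate 4 and 0 without any other array of those groups. In O2 it was 2557 and 3345 without replicates 2 and 3 of 21% O2, and 3496, 2064 and 2474 without replicates 1, 3 and 4 of 85% O2. Values that changed sign ran, at 6 h, from -0.41 to 0.41 for Sftpb, -0.070 to 0.42 for Cbs, -0.094 to 0.11 for Mpst, -0.13 to 0.29 for Abca3, -0.12 to 0.038 for Ethe1, -0.50 to 0.57 for Cth, -0.15 to 0.043 for Sqor, -0.30 to 0.78 for Sftpc and -0.49 to 1.15 for Ager. At 24 h they ran from -0.31 to 0.18 for Cth, -0.048 to 0.076 for Abca3 and -0.14 to 0.0046 for Ethe1. With time in vehicle they ran from -0.12 to 0.20 for Abca3 and -0.57 to 0.75 for Ager, and with time in NaHS from -0.34 to 1.11 for Ager and -0.17 to 0.13 for Abca3. In O2 they ran from -0.98 to 0.27 for Sftpc and -1.08 to 0.38 for Ager.

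Over the settings other than leaving out an array, named genes past the threshold kept direction and call in 346 of 571 cases with time in vehicle, 66 of 125 with time in NaHS and 802 of 831 in O2. Without 1 array they did so in 77 of 296, 3 of 64 and 498 of 576, and 0 of these genes changed sign. Named genes not past the threshold in the main fit passed in the same direction in 19 of 155, 4 of 94 and 9 of 94 cases. Without 1 array those passed in 2 of 80, 0 of 48 and 2 of 64. Scan day was not run as a block, since each experiment had 1 scan day and each slide 1 scan. Slide could not be a block in the GYY4137 experiment, where each slide held 1 oxygen level, and only the groups compared is the whole of that experiment.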

Other observations

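The gene families, the comparison of C1qa with C1qb and the look at gene brightness below were chosen after the values were seen.

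In 85% O2 some members of families with parts in cell division fell, and no enrichment was tested. Over all 34515 genes, 3536 rose and 1917 fell. Of 53 histone genes 25 fell and 9 rose (median -0.61), and under quantile normalization, normexp and median centring 24 to 26 fell. Of 21 centromere protein genes 14 fell and 1 rose (median -1.33), with 14 to 16 lower under those settings. Of 36 kinesin genes 10 fell and 4 rose. Of 23 late cornified envelope and small proline-rich genes, which belong to skin differentiation, 10 rose and 2 fell, and 9 or 10 rose under the other settings. Of 19 glutathione S-transferase genes 4 rose and 0 fell, with 1 lower under median centring.

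Genes lower with time in vehicle were often also lower in 85% O2. Of 72 and 1891 such genes among 32093 tested in both experiments, 42 were shared where independent lists give 4.24, and the Fisher odds ratio was 22.8 (13.9 to 37.9). Genes lower with time and higher in 85% O2 numbered 2, against 7.11 by independent lists. Genes higher in both numbered 35, against 12.5, with an odds ratio of 3.501. Why these genes overlap was not tested.

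C1qa rose with time in NaHS and lay above background on 4 of 4 NaHS arrays at 24 h. C1qb, of the same complement component, had a group mean of -1.98 ± 0.74 (SD, n = 4) with NaHS at 24 h and -1.84 ± 1.01 (SD, n = 4) with vehicle, so the C1qa difference did not extend to it. Of the macrophage list at 24 h, the median was -0.25 between NaHS and vehicle.

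The surplus of higher genes in 85% O2 lay outside the brightest genes. In 4 bins of genes from the dimmest to the brightest, 908, 1054, 952 and 622 were higher and 341, 326, 605 and 645 lower. Olfactory and vomeronasal receptor genes were called higher in 74 and lower in 22 of 652, in 41 and 32 under quantile normalization, 40 and 34 under normexp, and 49 and 26 under median centring. Their share of higher genes in the main fit was near that of all genes, 3536 of 34515.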
